A study of Arabidopsis thaliana with 48 samples.

How the data were processed

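Small RNAs of 18 to 30 nt from closed flower buds of Arabidopsis thaliana were sequenced from total extracts and from AGO1 immunoprecipitates (AGO1-IP). The plants were Col-0 wild type and 2 mutant alleles, atprmt5-2 and atprmt5-6, of PRMT5, a protein arginine methyltransferase. There were 2 libraries per genotype and fraction, described as biological duplicates, 12 libraries in all. The labels number the replicates 1 and 2 in total small RNA and 1 and 3 in AGO1-IP, but the names of the deposited files give the second total libraries the number 3 as well. Total and AGO1-IP libraries of a genotype may therefore share material, which the sources used here do not state. Each library was deposited as 4 tables, for reads of 21, 22, 23 and 24 nt, giving 48 tables.

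The deposited tables give RPM values for 428 annotated miRNAs, and the scaling of these RPM values by the authors was worked out from the values. Within a library and read length, every listed RPM was a whole multiple of the worth of 1 read, within a tolerance of 0.01 reads, so that read numbers and the authors' denominators were recovered for all tables but those for 24 nt in AGO1-IP. Each recovered denominator was taken as the number of reads of that length, so the RPM of different read lengths are not on a common scale. The values do not tell whether all or only mapped reads of that length were counted. A missing value was taken as 0 reads. Per the submitters' processing notes, TAIR10, Trimmomatic 0.36, Bowtie2 and SAMtools 1.9 were used; their roles, the handling of adapters and the number of mismatches are not given in the sources used here. Reads of identical mature sequences were spread evenly over the annotated copies: each of the 7 copies of miR166 held between 14.2% and 14.4% of that sequence's reads. Values of such copies are therefore not independent, and the 128 miRNAs tested held 97 distinct sequences. The wild-type total replicate 1 table for 23 nt held the read numbers of the 21 nt table for all 195 listed miRNAs. Its miRNA values were left out, and only its denominator was used. In AGO1-IP the 24 nt tables listed 1 or 2 miRNAs, too few to recover a denominator, so 24 nt shares were not computed and the 24 nt RPM of miR163 were used as deposited.

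The 21 nt reads numbered 571191 to 1397552 per library in total small RNA and 3750509 to 8166912 in AGO1-IP. Wild-type total replicate 1 was the shallowest library. Replicates of every group differed by more than sampling noise (chi-square per degree of freedom of 23.4 to 499), so no library was counted as a repeat of another. Floors of 3 reads and intervals at 95% cover counting error only.

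Before the data were examined, the design named an edgeR test on counts summed over read lengths. Because the deposited unit was RPM with a separate denominator for each length, the main test was instead limma 3.58.1 on log2(RPM + 1) of 21 nt reads, with miRNAs of mean RPM of at least 5 over the 12 libraries. A fold change on this scale understates the change of low miRNAs. The fit held 6 groups with 6 residual degrees of freedom, an intensity trend and no block, with calls at a Benjamini-Hochberg adjusted p under 0.05. Pooling the spread assumes that total and AGO1-IP libraries vary alike. Tested on simulated reads for atprmt5-2 against wild type in total small RNA, with 40 changed miRNAs among 428 in each of 10 simulations, limma recovered 72.7% of 2-fold and 99% of 4-fold changes with 8.42% of calls false. edgeR 4.0.16 recovered 63% and 93.5% with 3.69% of calls false. The 40 changed miRNAs were drawn from those of mean RPM of at least 5, and all simulated reads had a dispersion of 0.02. Larger spreads, such as those of miR161.1 (SE 0.29), miR168a-5p (SE 0.37) and miR843 (SE 0.71), were not simulated. These rates do not cover such miRNAs and may not describe the data in general. Loading means the log2 difference of AGO1-IP from total, and a loading difference is that of a mutant minus that of wild type.

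The 10 miRNA lists, fixed before the data were examined, were phasiRNA triggers, silencing machinery, phase change and flowering, auxin signalling, meristem and organ patterning, nutrient homeostasis, passenger strands, other Argonautes, pollen-associated and conserved families. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Single values per library were compared by exact two-sided permutation of labels within fraction or within genotype, which treats the 12 libraries as independent. Named miRNAs followed a rule fixed at the same time: the 8 largest changes per direction called in both alleles, the 5 largest per direction in each allele, the 8 largest per direction in wild-type loading, the 5 largest per direction in loading and allele differences, the 5 most abundant in wild type, and set guides such as miR168, miR162, miR403, miR390, miR161, miR393 and miR400. Among the set guides, miR828 was not abundant enough in 21 nt reads to be tested, and miR173-5p and miR472-5p were not among the miRNAs tested there either. Names outside the rule are stated as such.

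Alternatives fixed in advance were scaling to miRNA reads, DESeq2 1.42.0, no filter, 22 nt reads, sums over family and arm, only the groups compared, replicate blocks and leaving out each library. Added later were pseudocounts of 0.5 and 5, sums over identical sequences, edgeR on recovered reads with the authors' denominators or TMM, centring on the median miRNA, and a replicate block that keeps the first, or the second, total and AGO1-IP libraries of a genotype together. Both alleles share their wild-type libraries, so 100 simulations of unchanged groups were set beside their overlap. R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. All 428 miRNAs were matched to the TAIR10.1 annotation, from which coordinates are given.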

Results

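Closed flower buds of wild type, atprmt5-2 and atprmt5-6 gave 2 libraries each of total small RNA and of AGO1-bound small RNA. PRMT5, which places symmetric methyl marks on arginines, is encoded on chromosome 4 from 15132011 to 15136696 on the minus strand (AT4G31120). The tables hold miRNA reads only, so the mutated gene itself was not measured. Annotated miRNAs made up 23.0% to 32.9% of the 21 nt reads in total small RNA and 70.5% to 74.8% in AGO1-IP. Each library listed 195 to 241 miRNAs with 21 nt reads. The miR166 guide, which targets class III HD-ZIP transcripts, was the most abundant miRNA, with 22368 ± 1932 RPM (SD, n = 2) for miR166b-3p in wild-type total small RNA and 66812 ± 1197 RPM for miR166f in wild-type AGO1-IP. Both are copies of the same 21 nt sequence. Together miR165 and miR166 took 17.5% ± 1.87 (SD, n = 2) of wild-type 21 nt reads in total small RNA and 58.1% ± 0.116 in AGO1-IP.

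The design asked first how the prmt5 mutations affect miRNA accumulation. miR843 was at 2.77 ± 1.44 RPM in wild-type total small RNA, 42.9 ± 38.9 RPM in atprmt5-2 and 96.3 ± 40.9 RPM in atprmt5-6 (SD, n = 2). miR161.1, which targets transcripts of pentatricopeptide repeat proteins, rose from 1426 ± 626 RPM to 2909 ± 564 and 3108 ± 418 RPM. The miR858 guides, which target MYB transcription factor transcripts, fell: miR858b was at 121 ± 34.1 RPM in wild type, 25.4 ± 1.24 RPM in atprmt5-2 and 35.5 ± 5.69 RPM in atprmt5-6. miR858a went from 237 ± 114 RPM to 78.5 ± 14.7 RPM in atprmt5-2 and to 67.3 and 75.2 RPM in the atprmt5-6 libraries. miR5017-5p fell from 182 ± 47.7 RPM to 50.5 ± 4.73 and 39.2 ± 5.90 RPM.

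Of 128 miRNAs tested with limma, 4 were higher and 16 lower in atprmt5-2, and 5 were higher and 21 lower in atprmt5-6. The median miRNA lay at a log2 fold change of -0.44 in atprmt5-2 and -0.67 in atprmt5-6, and all 16 and 21 lower calls lay below that median, 6 and 3 of them by more than 1 on the log2 scale. miR843 rose by a log2 fold change of 3.24 (SE 0.71, adjusted p = 0.0226) in atprmt5-2 and 4.68 (SE 0.71, adjusted p = 0.00273) in atprmt5-6, which is 3.68 and 5.35 above the median. miR5637 had 0 reads in both wild-type libraries and 16 and 37 reads in the mutants, at least 4.28-fold and 8.64-fold higher against a floor of 3 reads over the wild-type group (adjusted p = 0.000374 and 3.07e-05). miR858b changed by -2.18 (SE 0.31, adjusted p = 0.00168) and -1.72 (SE 0.31, adjusted p = 0.00602), or -1.74 and -1.05 relative to the median. miR165b rose by 0.87 and 1.06 (adjusted p = 0.0251 and 0.00919). Its identical copy miR165a-3p passed in atprmt5-6 only, at 1.02 (adjusted p = 0.0234), and a difference between the alleles was not called for it.

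The calls shared by both alleles were 4 higher miRNAs (miR843, miR5637, miR161.1 and miR165b) and 13 lower. Among the lower were miR5017-5p, miR858b, miR858a, miR867, miR159c, miR171b-3p, miR319c and miR860. miR171c-3p, the identical copy of miR171b-3p and named outside the rule, was lower in atprmt5-2 but not called in atprmt5-6 (-0.78, adjusted p = 0.0559). miR159c belongs to a family that targets MYB transcripts, miR171 targets GRAS-domain regulators and miR319 targets TCP transcripts. Mean log2 fold changes over the alleles ran from -1.98 for miR5017-5p to -1.23 for miR860 in this group. miR845a, a pollen-associated miRNA, fell from 75.8 ± 3.26 RPM to 37.7 ± 0.619 and 35.5 ± 7.47 RPM. The remaining 4 lower miRNAs, named after their values were seen, were miR780.1, miR824-5p, miR869.2 and miR780.2. Independent lists would share 0.156 higher and 2.62 lower miRNAs, and unchanged groups simulated against the same wild-type libraries shared a mean of 0.01. Unchanged groups give few calls, so this low mean does not test whether alleles that both have calls agree. The fold changes of the alleles had a covariance of 0.678 against a simulated 0.105 (r 0.88 against 0.51, across miRNAs, which are not independent replicates). Wild type has only 2 libraries and was not split, so part of the excess may come from the shared controls. Differences between replicates correlated at 0.63 between the mutants, but at -0.10 and -0.07 between wild type and each mutant. The alleles may therefore also share a replicate effect, which cannot be told apart here from a shared genotype effect.

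Called in 1 allele only among the largest changes were miR8183 (log2 fold change -2.24, adjusted p = 0.00107) and miR163 (-1.81, adjusted p = 0.0433) in atprmt5-2, and miR171b-5p (-1.87, adjusted p = 0.00602) and miR824-3p (-1.56, adjusted p = 0.0415) in atprmt5-6. miR8183 was near the floor in atprmt5-2, at 0.849 RPM where 1 read was worth 0.792 and 0.907 RPM, against 7.79 RPM in wild type. In atprmt5-6 miR163 stood at -1.61 (adjusted p = 0.0511). Its 21 nt reads are shorter than its 24 nt form. That form differed by a log2 value of -0.56 between mutants and wild type in total small RNA (exact permutation p = 0.133). No miRNA was called by limma between the alleles in total small RNA, where 7 had an unadjusted p under 0.05 and edgeR and DESeq2 also called 0. Scaling to miRNA reads and centring on the median miRNA called 1 each, and further settings with calls are given below under processing. In AGO1-IP the same comparison gave 0 calls by limma, edgeR and DESeq2, and 1 miRNA at an unadjusted p under 0.05.

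Without wild-type total replicate 1, the shallowest library, the counts dropped to 3 in atprmt5-2 (miR5637, miR858b and miR8183) and 2 in atprmt5-6 (miR5637 and miR5017-5p), and the calls of miR843, miR161.1 and miR165b were lost at log2 fold changes of 2.84, 0.62 and 0.69 in atprmt5-2 and 4.28, 0.73 and 0.88 in atprmt5-6. Over the fits that each left out 1 library of the groups compared, miR843 ran from 2.18 to 4.30 in atprmt5-2 and from 4.24 to 5.12 in atprmt5-6, miR161.1 from 0.62 to 1.55 and 0.73 to 1.65, and miR165b from 0.69 to 1.05 and 0.81 to 1.31. The call of miR161.1 was also lost without either total library of the mutant in each allele, and that of miR165b without atprmt5-2 replicate 1. The balance of directions rests on the scaling: with TMM in edgeR it was 5 higher and 3 lower in atprmt5-2 and 5 and 2 in atprmt5-6, with DESeq2 5 and 2 and then 5 and 6, and after centring on the median miRNA 14 and 4 and then 20 and 2. No named call in these comparisons changed sign under any scaling. Most of the 16 and 21 lower calls were nevertheless lost with TMM, DESeq2 or centring, so they depend on the scaling.

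**Figure D1:**
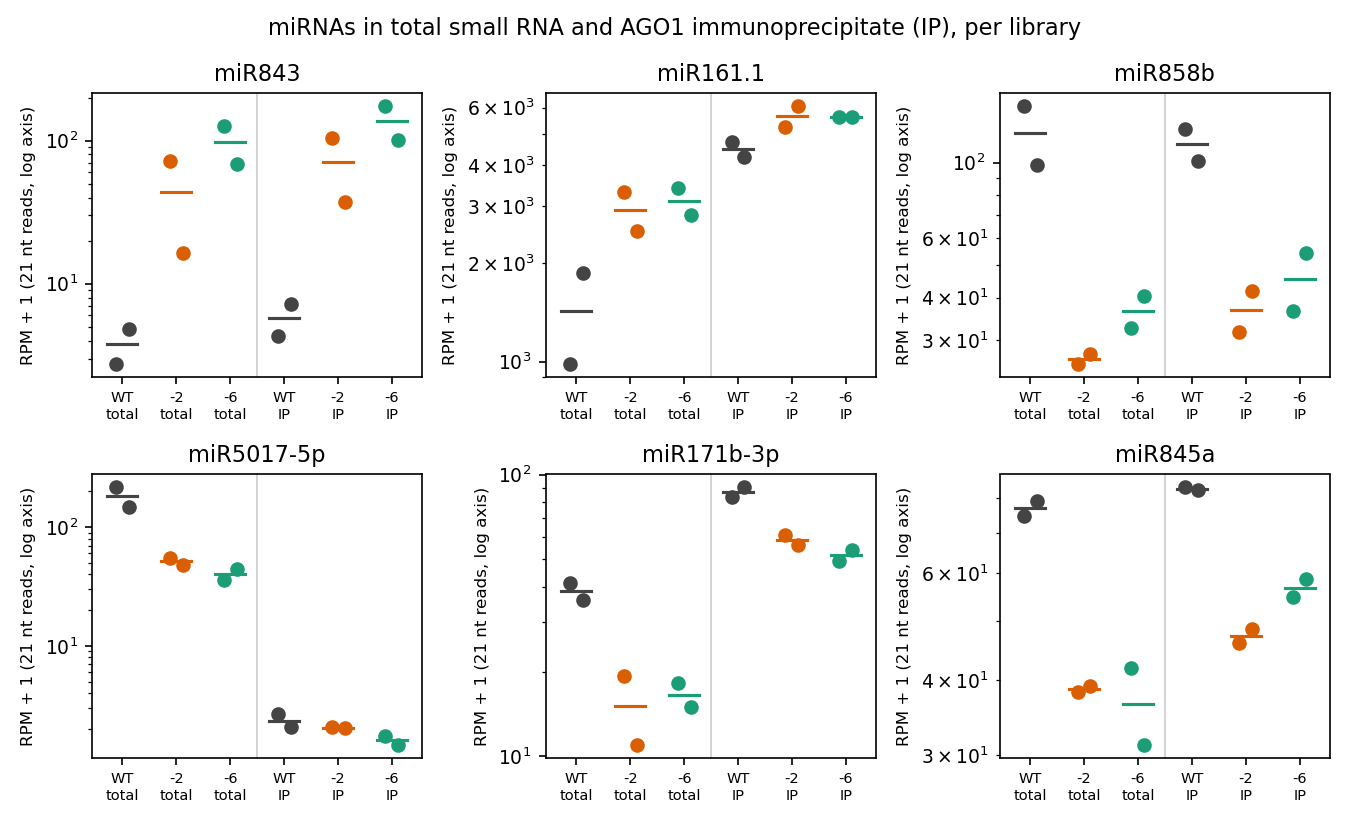
RPM + 1 of 6 miRNAs (21 nt reads, log axis) in each library, by genotype and fraction; points are libraries (n = 2 per group) and lines are group means. miR843 lies between 15.4 and 125 RPM in mutant total small RNA and at 1.75 and 3.79 RPM in wild type, while miR5017-5p is near 1 RPM in every AGO1-IP group.

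Several lists of functionally related miRNAs were followed in total small RNA. The nutrient homeostasis list, which holds the sulfate, copper and phosphate guides miR395, miR397, miR398, miR399, miR408 and miR827, ranked above the other miRNAs in atprmt5-2 (camera adjusted p = 0.0153) and atprmt5-6 (adjusted p = 0.0137). These calls were lost with an estimated correlation (camera adjusted p = 0.325 and 0.313). The list holds identical copies of miR395, miR398 and miR399 guides. Summed over family and arm it had 7 members and did not pass (camera adjusted p = 0.743 and 0.437). The list's median log2 fold change was 0.33 in atprmt5-2 and -0.21 in atprmt5-6, where its mean was 0.17, and 0 of its 14 tested members was called in either allele, also when adjusted over the list alone. Copper guides in particular differed between replicates: miR398b-3p was at 1758 and 372 RPM in the atprmt5-2 libraries, 1370 and 148 RPM in the atprmt5-6 libraries, and 618 and 444 RPM in wild type.

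The other lists did not pass, with camera adjusted p between 0.584 and 0.651 in atprmt5-2 and between 0.348 and 0.903 in atprmt5-6. Among 77 tested members of conserved families, 1 rose and 4 fell in atprmt5-2, and 2 rose and 9 fell in atprmt5-6. Adjusted over the list alone these were 1 and 4, and 2 and 8. Of 23 meristem and organ patterning members, 1 rose and 4 fell in atprmt5-2 and 2 rose and 4 fell in atprmt5-6, or 1 and 5 and then 2 and 7 adjusted over the list alone. The phasiRNA triggers had 1 of 7 members higher in each allele, miR161.1, and miR390b-5p lower in atprmt5-6 (-0.87, adjusted p = 0.0431). The identical copy miR390a-5p was not called there (-0.90, adjusted p = 0.0511), and the 2 copies summed were (-0.89, adjusted p = 0.0282). Adjusted over the list alone, 1 and 3 triggers were lower. In the phase change and flowering list 2 of 7 members fell in atprmt5-6, miR172d-3p and miR172b-3p (named after their values were seen), while their identical copies miR172c and miR172a were not called (adjusted p = 0.0645 and 0.0511). Summed over copies both sequences were lower (adjusted p = 0.0261 and 0.0265). Passenger strands fell for 3 of 19 in atprmt5-6, and pollen-associated miRNAs for 1 of 2 in each allele. Of 10 auxin signalling members, 0 was called in atprmt5-2 and 1 in atprmt5-6, and of 7 members of the other Argonautes list 0 and 2. The 5 members of the silencing machinery list gave 0 calls in limma, with 0 also when adjusted over the list alone. miR168a-5p, the guide against AGO1 mRNA, was at 2131 ± 623 RPM in wild type, 1275 ± 52.4 RPM in atprmt5-2 and 1247 ± 130 RPM in atprmt5-6 (adjusted p = 0.184 and 0.133). Its relatives in this list were near the median too, with miR162a-3p, which targets DCL1, at -0.39 and -0.60, and miR403-3p, which targets AGO2, at -0.36 and -0.43.

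The AGO1-bound pool was the other readout named in the design. In AGO1-IP miR843 was at 4.74 ± 2.05 RPM in wild type, 69.6 ± 46.8 RPM in atprmt5-2 and 136 ± 51.2 RPM in atprmt5-6 (SD, n = 2). miR825 rose in atprmt5-2 from 16.1 ± 2.52 to 54.2 ± 0.426 RPM, and miR5024-3p from 3.43 ± 0.008 to 19.2 ± 8.32 RPM. In atprmt5-6 both were above wild type without a call, miR825 at 38.3 RPM (log2 fold change 1.21, adjusted p = 0.0531 by limma) and miR5024-3p at 11.7 RPM (1.52, adjusted p = 0.107). miR858a and miR858b fell in atprmt5-2, from 282 ± 38.5 to 85.7 ± 5.76 RPM and from 112 ± 17.6 to 35.7 ± 7.12 RPM. The AGO1-bound miR168a-5p was at 1256 ± 142 RPM in wild type, 1677 ± 981 RPM in atprmt5-2 and 1085 ± 25.3 RPM in atprmt5-6.

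limma called 3 higher and 2 lower miRNAs of 128 in atprmt5-2 and 1 higher and 0 lower in atprmt5-6. At an unadjusted p under 0.05 there were 9 higher and 11 lower miRNAs in atprmt5-2 and 11 higher and 12 lower in atprmt5-6, and in atprmt5-6 DESeq2 called 3 higher and 2 lower and edgeR 4 and 2 with the authors' denominators or 5 and 0 with TMM. miR843 was the 1 miRNA called by limma in both alleles (log2 fold change 3.49, adjusted p = 0.0167, and 4.58, adjusted p = 0.00982), where independent lists would share 0.023. The number shared depends on the method, with 5 higher and 2 lower using replicate blocks, 4 and 2 in edgeR, 3 and 2 in DESeq2, 4 and 0 with TMM and 3 and 1 with identical sequences summed. miR858b, at -1.63 in atprmt5-2 (adjusted p = 0.0167), stood at -1.34 in atprmt5-6 (adjusted p = 0.0531). miR858a was at -1.70 (adjusted p = 0.0167) and -1.26. The medians were 0.04 and -0.14. The covariance of the allele fold changes was 0.426 against a simulated 0.101. As in total small RNA, shared controls or replicate differences common to the mutants (r 0.64) may add to this excess. The nutrient homeostasis list ranked higher in atprmt5-6 (camera adjusted p = 0.0158) and not in atprmt5-2 (adjusted p = 0.0693), and that difference was not called (adjusted p = 0.611). In atprmt5-6 the call was lost with an estimated correlation (camera adjusted p = 0.329) and with sums over family and arm (adjusted p = 0.7235).

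In atprmt5-2 all 5 AGO1-IP calls were lost without wild-type replicate 1, without wild-type replicate 3 or without atprmt5-2 replicate 1, and the call of miR843 in atprmt5-6 was lost without wild-type replicate 1 or without atprmt5-6 replicate 1. Over the fits that each left out 1 library the log2 fold changes in atprmt5-2 stayed between 2.75 and 4.22 for miR843, 1.54 and 1.85 for miR825, 1.69 and 2.56 for miR5024-3p, -1.84 and -1.56 for miR858a and -1.83 and -1.43 for miR858b, and between 4.19 and 4.97 for miR843 in atprmt5-6. Scaled to miRNA reads, atprmt5-2 had 4 higher and 0 lower.

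Which miRNAs AGO1 held, relative to their amount in total small RNA, was first compared within wild type. Guide strands of the miR165 and miR166 families, of miR396b-5p, which targets growth-regulating factors, and of miR159b-3p were enriched in AGO1-IP. miR165b went from 10005 ± 1747 RPM in total small RNA to 60512 ± 3789 RPM in AGO1-IP, and miR396b-5p from 9547 to 39948 RPM. miR168a-3p, the passenger strand of miR168a, went from 954 to 6.98 RPM. miR390a-5p, a guide known for its loading into AGO7, went from 1786 ± 262 to 136 ± 2.08 RPM.

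limma called 26 higher and 26 lower of 128, of which 17 and 23 were distinct sequences, and the median miRNA lay at 0.23. The higher calls included miR5637, with 0 reads in wild-type total small RNA and 1.36 RPM in AGO1-IP. That value lies below the floor of 3 reads over the wild-type total group (1.59 RPM), so this call does not show enrichment. miR165b was enriched by a log2 difference of 2.61 (SE 0.22, adjusted p = 2.69e-06), miR165a-3p by 2.46, miR396b-5p by 2.08, miR159b-3p by 1.73 and miR161.1 by 1.72, and miR839-5p was 3.72-fold higher. The 7 identical copies of miR166 lay between 1.58 and 1.60, little above the rise of annotated miRNAs as a whole. miR168a-3p stood at -6.91 (SE 0.41, adjusted p = 3.18e-07), miR5017-5p at -6.27, miR390a-5p at -3.70 and miR390b-5p at -3.57. miR158a-5p had 2 reads in wild-type AGO1-IP, a ratio of 1048 in favour of total small RNA with an exact Poisson interval of 290 to 8653. miR165a-5p had 0, at least 197-fold lower against a floor of 3 reads over the group. The sequence shared by miR166a-5p and miR166b-5p had 2 reads in AGO1-IP, and miR167a-3p and miR861-3p had 1 each.

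Of 19 passenger strands tested, 16 were lower and 0 higher (camera adjusted p = 3.92e-10, and adjusted p = 0.263 with an estimated correlation). Of 23 meristem and organ patterning miRNAs 15 were higher and 0 lower (adjusted p = 1.22e-05, and adjusted p = 0.478 with an estimated correlation), and these 23 hold 13 distinct sequences. The other 8 lists had a camera adjusted p of 0.796. In the silencing machinery list miR162a-3p (1.37), miR162b-3p (1.47) and miR403-3p (1.27) were higher, while miR168a-5p stood at -0.74 (adjusted p = 0.138). With total and AGO1-IP libraries of a number kept together, limma called miR168a-5p and miR168b-5p lower, as given below under processing. All 7 tested members of the other Argonautes list were called, 4 higher and 3 lower. Scaling decides the sign of moderate enrichments, because miRNAs took a larger part of the 21 nt reads in AGO1-IP: scaled to miRNA reads there were 4 higher and 86 lower, with a median of -1.25, and miR162a-3p, miR162b-3p and miR403-3p turned to -0.15, -0.06 and -0.26. With TMM or DESeq2 there were 18 higher and 34 lower, and after centring on the median miRNA 60 higher and 23 lower.

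**Figure D2:**
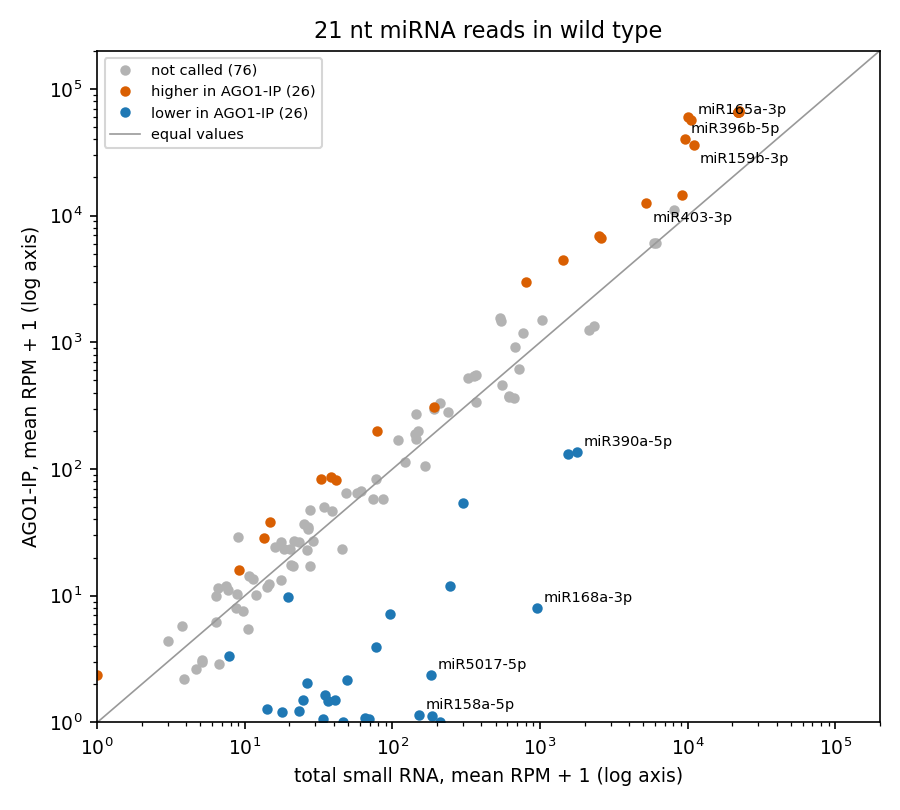
Mean RPM + 1 of 128 miRNAs in wild-type AGO1-IP against wild-type total small RNA (log axes; n = 2 libraries per fraction), colored by the limma call; the line marks equal values. The 26 lower miRNAs reach far below the line, and miR165a-3p and miR396b-5p lie above it; scaled to miRNA reads 4 were higher and 86 lower.

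The same contrast in the mutants gave 47 higher and 24 lower in atprmt5-2 and 52 higher and 25 lower in atprmt5-6, with medians of 0.62 and 0.69. Passenger strands were lower for 16 of 19 in each mutant (adjusted p = 1.07e-11 and 5.42e-12, or adjusted p = 0.185 and 0.174 with an estimated correlation), and meristem and organ patterning miRNAs higher for 18 of 23 (adjusted p = 0.000207 and 0.000203, or adjusted p = 0.70 and 0.699 with an estimated correlation). Whether loading itself differed between mutant and wild type was tested as a difference of differences. For atprmt5-2 limma called 0 miRNAs, with 18 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. For atprmt5-6 it called miR5637 alone, at -2.39 (adjusted p = 0.042), with 16 at an unadjusted p under 0.05 and 0 calls by edgeR or DESeq2. The next smallest unadjusted p in both alleles was that of miR5017-5p, at 1.62 in each (adjusted p = 0.168 and 0.173). The median loading difference was 0.42 and 0.46, and -0.08 and -0.03 with TMM. With scaling to miRNA reads, 8 higher and 2 lower were called in atprmt5-2 and 7 higher and 3 lower in atprmt5-6. With TMM the loading split was 12 higher and 35 lower in atprmt5-2 and 4 and 33 in atprmt5-6, with DESeq2 10 and 33 and then 17 and 33, and scaled to miRNA reads 3 and 46 and then 3 and 52.

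Read length was compared next. Neither the ratio of 22 nt to 21 nt reads nor the test of miR163 at 24 nt was in the fixed design. The ratio was chosen after values had been seen, and its read numbers are the recovered denominators. In both mutants there were fewer 22 nt reads per 21 nt read than in wild type: 0.204 ± 0.0234 in atprmt5-2 and 0.199 ± 0.0156 in atprmt5-6 against 0.301 ± 0.0058 in wild-type AGO1-IP, and 0.741 ± 0.0725 and 0.753 ± 0.0272 against 0.891 ± 0.0738 in total small RNA (SD, n = 2). All 8 mutant libraries lay below both wild-type libraries of their fraction. The log2 difference over both fractions was -0.42 (exact permutation p = 0.00444, the smallest these arrangements give, adjusted p = 0.0178 over 8 measures). That p takes the 12 libraries as independent, and if total and AGO1-IP libraries of a number share material it is 0.0667 (exact permutation, the smallest possible). Within a single fraction an exact permutation cannot go below p = 0.0667. The 24 nt form of miR163, which targets methyltransferase transcripts of the SABATH family, was lower in all 8 mutant libraries, at 4267 ± 620 RPM in wild-type AGO1-IP, 2057 ± 471 RPM in atprmt5-2 and 2656 ± 747 RPM in atprmt5-6, on denominators that were not recovered in AGO1-IP. Its log2 difference over both fractions was -0.72 (exact permutation p = 0.0133, adjusted p = 0.0355, or exact permutation p = 0.133 with such libraries kept together).

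**Figure D3:**
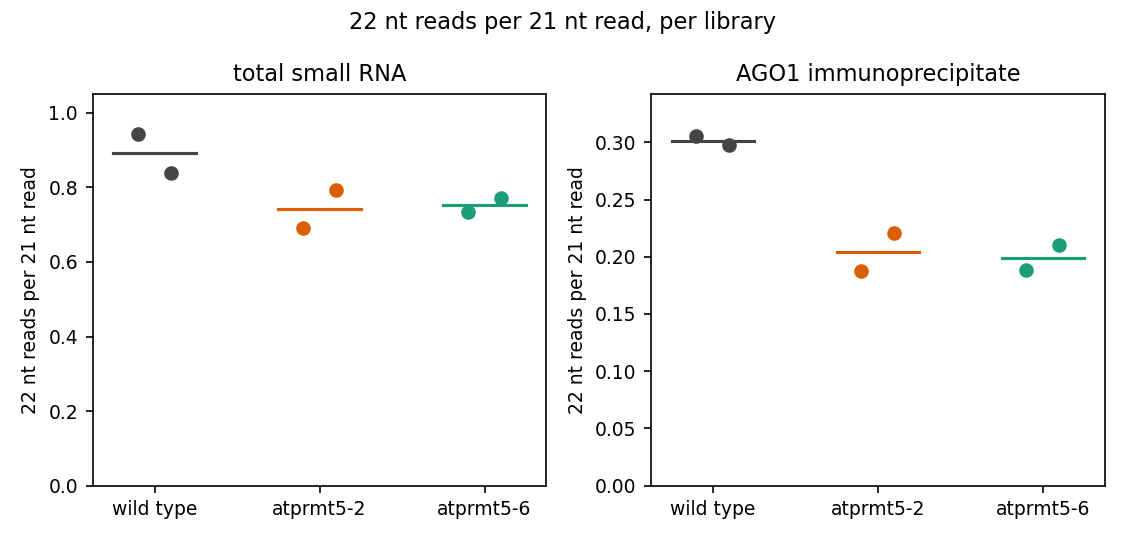
Number of 22 nt reads per 21 nt read in each library by genotype, in total small RNA and AGO1-IP; points are libraries (n = 2 per group) and lines are group means, on axes from 0. Mutant AGO1-IP libraries lie between 0.188 and 0.221, below both wild-type libraries at 0.297 and 0.306.

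Among annotated miRNA reads, the 22 nt share was under 0.3 percent in every library. No 22 nt table listed a miRNA annotated as shorter than 22 nt, so 22 nt forms of 21 nt miRNAs are not part of this share, which depends on the miRNAs annotated at 22 nt or longer. It was 0.0688 percentage points lower in AGO1-IP than in total small RNA (difference -0.0688, exact permutation p = 0.00926, adjusted p = 0.00926 over 6 measures), and the 23 nt share differed by -0.0595 points (exact permutation p = 0.00926) over 11 libraries. With libraries of a number kept together, the exact permutation p was 0.0312 for 22 nt and 0.0625 for 23 nt. Averaged per miRNA over 49 miRNAs the 22 nt difference took the opposite sign, at 0.381 points. Between mutants and wild type the 22 nt share differed by -0.016 points (exact permutation p = 0.351, adjusted p = 0.401), with the opposite sign when averaged per miRNA (0.24 points, exact permutation p = 0.0133), and the 23 nt share by -0.0203 points (exact permutation p = 0.0667, adjusted p = 0.133). The 23 nt share had 1 wild-type total library. With a library left out, the differences ran from -0.0243 to -0.0078 for 22 nt and from -0.0213 to -0.0006 for 23 nt. miR173-5p, the 22 nt guide that starts TAS1 and TAS2 siRNA production, was at 283 ± 2.97 RPM of 22 nt reads in wild-type AGO1-IP, 647 ± 160 RPM in atprmt5-2 and 481 ± 24.1 RPM in atprmt5-6. These RPM use 22 nt denominators, which were themselves lower in the mutants. Over 22 miRNAs tested in 22 nt reads of AGO1-IP the median log2 fold change was 0.39 and 0.42 with 22 nt denominators, and -0.13 and -0.17 with 21 nt denominators. limma called 0 of these 22 in AGO1-IP in either allele.

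The named miRNAs that stood out map as follows in TAIR10.1. miR843 lies on chromosome 3 from 17742147 to 17742167 on the plus strand (AT3G48057), outside protein-coding genes. miR858b and miR858a lie on chromosome 1, from 26772907 to 26772927 on the plus strand and from 26773695 to 26773715 on the minus strand. The miR858b sequence has 2 exact sites in the nuclear genome. miR161.1 lies on chromosome 1 from 17825731 to 17825751, outside protein-coding genes. miR5637 lies on chromosome 2 from 12270341 to 12270361 on the minus strand, in an intron of AT2G28620 and on its strand. miR5017-5p lies on chromosome 4 from 11963005 to 11963025 on the minus strand, opposite an exon of AT4G22760. miR5024-3p lies in an intron of AT1G44100 on chromosome 1 from 16766285 to 16766305. miR860 lies in an exon of AT5G26030 on chromosome 5 from 9098876 to 9098896.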

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

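All tests weighing an explanation here were chosen after the result had been seen, and so was every comparison of total 21, 22 and 23 nt reads.

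The loading difference of miR5637 in atprmt5-6 was called because mutant and wild type differed in the contrast of AGO1-IP with total small RNA (-2.39, adjusted p = 0.042 in limma). It had 0 reads in wild-type total small RNA, and the call was lost in each of the 8 fits that left out a library. The meristem and organ patterning list ranked lower in the atprmt5-6 loading difference (camera adjusted p = 0.0423, adjusted p = 0.99 with an estimated correlation), with a median of 0.05 against 0.46 for all tested miRNAs. The silencing machinery list ranked lower in atprmt5-6 than in atprmt5-2 in AGO1-IP (camera adjusted p = 0.00971). That call was lost with an estimated correlation (camera adjusted p = 0.798) and with sums over family and arm (adjusted p = 0.124). In AGO1-IP, atprmt5-2 replicate 3 held 12987 RPM of miR162a-3p against 5881 RPM in replicate 1.

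Fewer 22 nt reads per 21 nt read were found in both alleles and both fractions. A gain of 21 nt miRNA reads is argued against: without annotated miRNA reads the mutant ratio was 0.604 of wild type in AGO1-IP and 0.86 in total small RNA, with no overlap of libraries. Depth is argued against in AGO1-IP, where the 3 mutant libraries at least 95% as deep as the shallower wild-type library reached at most 0.221, below the lower wild-type value of 0.297. In total small RNA it cannot be told apart, because all 4 mutant libraries (at most 0.792) were deeper than wild-type replicate 1, and only replicate 2 of wild type (0.839) had a depth like theirs. A size selection towards shorter inserts would lower 23 nt reads as well; in AGO1-IP 23 nt reads per 21 nt read were at 1.01 of wild type, but in total small RNA they were at 0.785 with overlapping libraries, so there it cannot be told apart from a genotype difference. That the alleles make or keep fewer 22 nt small RNAs may be one reading, which no test here addressed.

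The median miRNA was lower in total small RNA of both alleles. Reads taken by miR165 and miR166 do not account for it, as the median stayed at -0.37 in atprmt5-2 and -0.62 in atprmt5-6 when scaled to the other 21 nt reads. Set against wild-type total replicate 2 alone, the mutant library medians were -0.0687 and -0.54 in atprmt5-2 and -0.36 and -0.62 in atprmt5-6. The shallow wild-type replicate 1 is thus argued against as the whole source in atprmt5-6, and in atprmt5-2, where the libraries part, it cannot be told apart from a genotype difference. A genotype effect stays open and untested, and TMM or DESeq2 scaling removes most of the shift by construction.

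miR843 was higher in both alleles and both fractions. A single library is argued against, because the lowest mutant library was 4.07 times the highest wild-type library or more in each fraction. Reads from another identical site are argued against by its 1 exact site in the nuclear genome. Near-identical and organellar sites were not examined, and the number of mismatches allowed is not given. Linkage to the mutated gene is argued against by its place on chromosome 3 rather than chromosome 4. A loss of PRMT5 that raises miR843 is therefore a hypothesis consistent with these values, although the call is lost without wild-type total replicate 1 (log2 fold change 2.84, adjusted p = 0.154 in atprmt5-2 and 4.28, adjusted p = 0.0573 in atprmt5-6 by limma) and the size differed between replicates, with 70.5 and 15.4 RPM in atprmt5-2 total small RNA.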

How the results depend on the processing

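All alternatives marked here as added, and all tests weighing an explanation, were chosen after the results had been seen.

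Counts of called miRNAs moved as follows where an alternative changed them by more than 1.5 times. In total small RNA of atprmt5-2 (20 calls), scaling to miRNA reads gave 38, DESeq2 7, no filter 32, 22 nt reads 3, only the groups compared 3, blocks within each fraction 33, and the added TMM scaling 8. In atprmt5-6 (26 calls), scaling to miRNA reads gave 55, DESeq2 11, 22 nt reads 0, only the groups compared 6, blocks 67 and TMM 7. For calls shared by both alleles (17), these were 37 with scaling to miRNA reads, 7 with DESeq2, 0 with 22 nt reads, 3 with only the groups compared, 31 with blocks and 6 with TMM. Between the alleles (0 calls), scaling to miRNA reads gave 1, no filter 2, sums over family and arm 1, a pseudocount of 0.5 1, sums over identical sequences 1 and centring on the median 1.

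In AGO1-IP of atprmt5-2 (5 calls), no filter gave 1, 22 nt reads 0, only the groups compared 0, blocks 9, sums over identical sequences 8 and edgeR with the authors' denominators 8. In atprmt5-6 (1 call), scaling to miRNA reads gave 2, DESeq2 5, no filter 0, 22 nt reads 0, sums over family and arm 2, only the groups compared 16, blocks 7, sums over identical sequences 4, edgeR 6, TMM 5 and centring 5. For calls shared by both alleles (1), the values were 2 with scaling to miRNA reads, 5 with DESeq2, 0 with no filter, 0 with 22 nt reads, 2 with family sums, 0 with only the groups compared, 7 with blocks, 4 with identical sequences summed, 6 with edgeR, 4 with TMM and 4 with centring.

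In wild-type loading (52 calls), scaling to miRNA reads gave 90, 22 nt reads 18 and centring 83. In atprmt5-2 loading (71 calls), DESeq2 gave 43, 22 nt reads 22 and TMM 47. In atprmt5-6 loading (77 calls), DESeq2 gave 50, 22 nt reads 21 and TMM 37. For the loading difference of atprmt5-2 (0 calls), scaling to miRNA reads gave 10. For atprmt5-6 (1 call) it gave 10, DESeq2 0, no filter 0, 22 nt reads 0, blocks 2, edgeR 0, TMM 0 and centring 2. Of 11 list tests past the threshold, 0 remained with an estimated correlation and 7 with family sums.

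Single values changed as follows. Scaled to miRNA reads, wild-type loading reversed for miR162a-3p (-0.15), miR162b-3p (-0.058), miR403-3p (-0.26), miR393b-5p (-1.08) and miR400 (-1.16), the last 2 not called by limma. As a mean of shares per miRNA, the 22 nt share differed by 0.381 between AGO1-IP and total and by 0.24 between mutants and wild type (exact permutation p = 0.0133), both reversed. The median of 22 nt values with 21 nt denominators was -0.26 and -0.50 in total small RNA of atprmt5-2 and atprmt5-6 (main -0.02 and -0.30), and -0.13 and -0.17 in AGO1-IP (main 0.39 and 0.42).

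Leaving out each library in turn gave 3 to 34 calls in total small RNA of atprmt5-2 and 2 to 31 in atprmt5-6, with 1 to 17 shared. In AGO1-IP it gave 0 to 3 and 0 to 1, with 0 to 1 shared. Loading gave 42 to 51 in wild type, 61 to 78 in atprmt5-2 and 49 to 69 in atprmt5-6. Loading differences gave 0 to 1 in atprmt5-2 and 0 in atprmt5-6, and the alleles 0. The 22 nt share of AGO1-IP against total ran from -0.0761 to -0.0614 and the 23 nt share from -0.0606 to -0.0464, the last without wild-type total replicate 2 (exact permutation p = 0.0556). Mutants against wild type ran from -0.0243 to -0.0078 for 22 nt and -0.0213 to -0.0006 for 23 nt, at -0.0206 without atprmt5-2 AGO1-IP replicate 3 (exact permutation p = 0.04). The 22 nt reads per 21 nt read ran from -0.46 to -0.38 and miR163 at 24 nt from -0.80 to -0.64 on the log2 scale.

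Of 174 named results, 63 were called: over 1012 alternatives 831 kept the call, 178 lost it and 3 reversed, with 17 kept in all and 31 in every fit with a library left out. The 111 not called gave 1851 alternatives, of which 1797 kept that state, 52 gained a call and 2 reversed. No source used here states that total and AGO1-IP libraries share an origin, though the names of the deposited files number the second libraries of both fractions 3. An added replicate block kept such libraries together. Mutants against wild type then gave -0.4191 for 22 nt reads per 21 nt read (exact permutation p = 0.0667, the smallest possible) and -0.7245 for miR163 at 24 nt (exact permutation p = 0.133). Both differences were unchanged, and with 15 arrangements neither could pass 0.05. AGO1-IP against total gave -0.0688 for the 22 nt share (exact permutation p = 0.0312, the smallest possible) and -0.0541 for 23 nt (exact permutation p = 0.0625). The latter used 10 libraries and 32 arrangements, against 64 for 22 nt, so its larger p does not show a weaker difference. In limma the added block gave 59, 79 and 86 loading calls in wild type, atprmt5-2 and atprmt5-6, with loading differences of 0 and 1, and called miR168a-5p (adjusted p = 0.037) and miR168b-5p (adjusted p = 0.046) lower in wild-type loading. Differences between replicates correlated at 0.77 between atprmt5-6 total and AGO1-IP, 0.48 in atprmt5-2 and 0.14 in wild type, and within total small RNA at -0.10 between wild type and atprmt5-2, -0.07 between wild type and atprmt5-6 and 0.63 between the mutants. Within AGO1-IP the same correlations were 0.23, 0.35 and 0.64, each from 2 replicate numbers.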

Other observations

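All tests in this part were chosen after the results had been seen, apart from the 22 nt alternative.

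The first base of the mature sequence ran with AGO1 enrichment in wild type. Of 89 tested miRNAs that start with U, 25 were higher and 5 lower in AGO1-IP, with a median log2 difference of 0.53. All 8 tested miRNAs that start with G were lower, with a median of -5.71, and these were passenger strands such as miR166a-5p and miR167a-3p, apart from miR861-3p. Those starting with A had 1 higher and 8 lower of 18, and those starting with C 0 higher and 5 lower of 13 by limma. With a preset correlation the camera adjusted p was 1.85e-11 for U and 2.77e-07 for G, and with an estimated correlation adjusted p = 0.0616 for both. In the mutants the same lists with an estimated correlation gave adjusted p = 0.0432 in atprmt5-2 and 0.0463 in atprmt5-6 for U and for G.

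In AGO1-IP, miRNAs that start with C had a median log2 fold change of 0.82 in atprmt5-2 and 1.09 in atprmt5-6 (camera adjusted p = 0.00467 and 0.00167, and adjusted p = 0.265 and 0.20 with an estimated correlation). The 13 members hold 9 distinct sequences, and 6 of the 13 belong to the miR395 family.

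The copper guides miR398b-3p and miR397b separated the replicates of the mutants more than those of wild type. miR398b-3p in AGO1-IP was at 4846 and 1027 RPM in atprmt5-2, 3215 and 422 RPM in atprmt5-6 and 1812 and 1273 RPM in wild type. miR397b in total small RNA was at 41.2 and 6.35 RPM, 23.6 and 2.33 RPM, and 36.8 and 15.2 RPM in the same order. miR408-3p did so in total small RNA but not in AGO1-IP of atprmt5-2, where replicate 1 was 1.54 times the other library against 1.80 times in wild type. miR398a-5p, from the passenger arm, went the other way in total small RNA of the mutants, at 30.1 and 131 RPM in atprmt5-2 and 15.7 and 437 RPM in atprmt5-6, but at 52.5 and 15.2 RPM in wild type. The first value of each pair is replicate 1, and these miRNAs were chosen after their values were seen.

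In 22 nt reads of total small RNA, limma called miR848, miR845b and miR856 lower in atprmt5-2 and 0 in atprmt5-6, where 4 had an unadjusted p under 0.05. This contrast depends on the 22 nt denominators: with 21 nt denominators 3 were lower in each allele, the same 3 in atprmt5-2 and miR848, miR4221 and miR472-3p in atprmt5-6.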
